A study of Mus musculus with 8 samples.

How the data were processed

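Transcripts of single cells from the distal colonic mucosa of 8 mice of 8 weeks of age were measured, 4 KO-labelled and 4 WT-labelled. Per the labels' protocols, muscle layers were stripped, the tissue was digested with Liberase TM and DNase I, red cells were lysed and dead cells were taken out with annexin V beads. Per the labels' protocols, 10x Chromium 3′ libraries were made on 1 day as 1 batch and sequenced paired-end on a HiSeq instrument. The submitters' processing notes name Cell Ranger 3.0.2 and the mm10 build. The tools behind the authors' cell filter, clustering and annotation are not given in the sources used here.

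The deposited matrix holds raw counts: whole numbers of UMIs for 31053 genes in 53080 cells, with no normalization by the authors found in the values. The deposited cell table gives a size factor per cell, a ratio that the authors computed as the cell's total over the geometric mean of all totals. The UMAP coordinates in the deposited table are a score without a unit and were used only to check the order of the cells. The authors also gave each cell a mouse, a genotype, 1 of 32 clusters, 1 of 11 classes and in part a subtype. The table and the matrix list the cells in different orders. Read in file order, 16 of 53080 size factors equalled the matrix totals over their geometric mean (tolerance 1e-06), and all 53080 did once the table was sorted by mouse and barcode. The UMAP columns follow the matrix order: 98.8% of the variance of axis 1 lay between the authors' clusters when read that way and 0.0739% when read by table line. Of the gene symbols 71 were duplicated, and genes were followed by their Ensembl identifier.

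Cells held 500 to 113660 UMIs, and the total per mouse ranged from 17.0 to 37.3 M. The authors' classes were joined into epithelial, stromal, lymphoid and myeloid cells. The 1316 cells that the authors named doublets were left out of the sums and kept in the denominators of the shares. The authors' subtype names were empty for all 10558 KO-labelled and 6727 of 13229 WT-labelled epithelial cells. Epithelial types were therefore assigned anew in the 10990 epithelial cells with under 50% mitochondrial UMIs, a limit chosen after seeing the data. The steps were 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 with igraph 0.11.9, which gave 23 clusters. A cluster was named from marker lists by genes at a log2 fold of at least 1 in at least 5% of its cells, with a pseudocount of 10 CPM. This gave 6 colonocyte-like clusters (4937 cells), 3 cycling-like (869), 2 deep crypt secretory-like (978), 2 goblet-like (705), 1 stem-like (343), 1 tuft-like (153) and 1 enteroendocrine-like (89). Among cells the authors had named, colonocyte-like clusters 6 and 11 held 71 and 22 enterocytes but 286 and 324 stem-progenitor cells. Deep crypt secretory-like cluster 13 held 1 deep crypt secretory and 152 secretory-progenitor cells. Goblet-like cluster 18 held 0 goblet and 167 secretory-progenitor cells. In colonocyte-like clusters 1, 2, 5 and 15, deep crypt secretory-like cluster 8 and goblet-like cluster 9, the authors' most frequent name matched. Another 4 clusters (2513 cells) stayed unnamed, and 3 were led by markers of B cells, fibroblasts and T cells. A type was tested for genes where at least 3 mice per group had 20 or more of its cells. The smallest compartment sums held 251 stromal, 398 lymphoid and 9 myeloid cells, all from mouse 8.

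The mouse was the replicate. Counts were summed per mouse and cell set and tested with edgeR 4.0.16 (TMM factors, filterByExpr, quasi-likelihood F test) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. DESeq2 1.42.0 was run beside it. CPM values of the named genes are scaled by the TMM factors; those of Spry2 by mouse are plain CPM of the sums. Shares of cell types were compared by a two-sided exact permutation test over 70 assignments, whose smallest p is 0.0286, for types of 50 or more cells. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served for the rest, and gene positions came from GENCODE M21. Intervals cover 95%.

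Lists of genes were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, with a preset inter-gene correlation of 0.01 and, beside it, with an estimated correlation. The function fry asked whether the genes of a list move one way on balance. The 24 lists with 305 genes, all found in the file, were MAPK pathway feedback and targets, ERBB ligands and receptors, FoxO targets, Wnt targets, the Notch pathway and lineage factors, proliferation, colonocyte, goblet, tuft and enteroendocrine genes, the type 2 epithelial axis, type 2 immune cytokines and receptors, interferon response, MHC class II, antimicrobial defence, NF-kB targets and chemokines, ion and water transport, tight junction, the unfolded protein response, lipid and bile acid nuclear receptor genes, stromal niche factors, extracellular matrix, immediate early and dissociation stress, and mitochondrially encoded genes. A list needed 5 tested members. Goblet, tuft, enteroendocrine, colonocyte and proliferation lists share genes with the markers that named the clusters.

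The grouping, tests, lists, marker lists and the rule for naming genes were fixed before the data were examined. By that rule the epithelial comparison names Spry2, Il33, up to 10 genes higher and 10 lower past an adjusted p of 0.05 without overlap between the groups, and from each list up to 4 members past 0.05 or else the 2 of smallest p. Other comparisons name up to 5 genes in each direction, and up to 4 members of a passing list past the threshold. With fewer than 10 genes past the threshold, the 5 of smallest p in each direction are named. Xist, Tsix, Ddx3y, Eif2s3y, Uty and Kdm5d, immunoglobulin and T cell receptor variable genes, and gene models called Gm with a number or Rik take no place, while other X-linked genes and other unnamed models can be named: 1 was passed over in each of epithelial, stromal, cycling-like and goblet-like cells and 4 in lymphoid cells. The 2 members of smallest p given for each passing list outside the epithelial sums, the values of Il33 in stromal cells and genes named under alternatives stand outside the rule and were chosen after their values were seen. Some genes that the rule or these additions select are not reported here. Tests of genes in the authors' subtypes were also added after the data were examined.

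Alternatives set before the data were examined were DESeq2, RLE size factors, no expression filter, leaving out each mouse, 50 cells per mouse and type, and an equal number of cells per type and mouse for epithelial sums. For shares they were an edgeR test of cell counts, the centred log ratio (0.5 added to each count) and only cells with 1000 or more UMIs. Chosen after seeing the data were epithelial cells under 50% mitochondrial UMIs, the same cells without the clusters led by other lineages, the sex read from Xist and Y-linked genes as a term, mouse number 1 to 4 against 5 to 8 as a term, both terms, and the epithelial share as a term. Also chosen then were macrophages without cells of 10 or more Jchain UMIs, stromal cells without cells of 10 or more UMIs of goblet genes, cycling-like cells without 1 cluster, and shares of non-epithelial cells or without epithelial cells of 50% or more mitochondrial UMIs. Of each sex, read from these genes, 2 mice carried each label. KO-labelled mice 2 and 3 had Y-linked transcripts and mice 6 and 7 Xist, so within that label sex and mouse number cannot be told apart. WT-labelled mice 4 and 5 had Y-linked transcripts and mice 1 and 8 Xist. Chi-square per degree of freedom between mice of a label was 9.57 or more, so that no library duplicated another of its label. Pairs across labels were not compared.

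The gene test was tested on simulated data at the depth of each cell set, with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 32% and 86% in epithelial, 43% and 80% in stromal, 44% and 84% in lymphoid, 38% and 78% in myeloid, 48% and 78% in stem-like, 54% and 89% in cycling-like, 55% and 93% in colonocyte-like, 12% and 77% in goblet-like and 62% and 85% in deep crypt secretory-like cells. With no change simulated it called 0 genes, except 1 in stem-like and 2 in deep crypt secretory-like cells. With changes simulated, false calls were 10 of 128 in epithelial, 9 of 132 in stromal and 8 of 136 in lymphoid cells. They were 13 of 129 in myeloid, 13 of 139 in stem-like and 8 of 151 in cycling-like cells. In colonocyte-like, goblet-like and deep crypt secretory-like cells they were 4 of 152, 6 of 95 and 16 of 163. Genes were simulated independently, without variation shared between them, so these rates may not hold for the real sums.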

Results

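Single cells of the distal colonic mucosa were profiled from 8 mice of 8 weeks of age by droplet-based sequencing of transcript 3′ ends. The 4 KO-labelled mice (mice 2, 3, 6 and 7) carried a floxed Spry2 gene together with Cre recombinase under the Villin promoter, which is active in intestinal epithelial cells. The 4 WT-labelled mice (mice 1, 4, 5 and 8) were floxed littermates without Cre. The design asks how the cells of the colon differ in their transcripts when Sprouty2, an inhibitor of receptor tyrosine kinase signalling, is deleted in the epithelium. The deposited matrix held 53080 cells and 31053 genes, with 500 to 113660 UMIs (unique molecular identifiers, each counting 1 captured transcript) per cell. Total UMIs per mouse were 17.0, 19.4, 20.2, 27.4, 37.3, 28.2, 19.0 and 22.1 M (mega) for mice 1 to 8, from 3302 to 10101 cells. They came to 21.7 ± 4.36 M in KO-labelled and 25.97 ± 8.66 M in WT-labelled mice (SD, n = 4 each; exact permutation p = 0.514). The libraries differed in a way that the groups did not explain. Of the epithelial cells, those with 50% or more mitochondrial UMIs made up 78.8, 79.6, 69.0, 53.5, 37.2, 18.5, 13.6 and 11.1% in mice 1 to 8. They averaged 70.2 ± 12.1% in mice 1 to 4 and 20.1 ± 11.8% in mice 5 to 8 (SD, n = 4 each, exact permutation p = 0.0286). That division of the mice was chosen after seeing the data, so its p-value does not test it. The same share was 45.2 ± 34.0% in KO-labelled and 45.1 ± 28.4% in WT-labelled mice (exact permutation p = 1). In the text, mean CPM values (UMIs scaled to a common library total) are given with the SD over 4 mice per group and log2 fold changes, KO-labelled over WT-labelled, with their SE.

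On average, Spry2 transcripts were present in the epithelial cells of the KO-labelled mice at about the level of the WT-labelled mice. Spry2 (ENSMUSG00000022114), the floxed gene, measured 22.2 ± 18.2 CPM in KO-labelled and 23.5 ± 11.6 CPM in WT-labelled epithelial sums (2156 UMIs in all; exact permutation p = 0.857). The KO-labelled mice 2, 3 and 6 had 10.4, 13.3 and 15.7 CPM, mouse 7 had 49.3 CPM, and the WT-labelled mice 1, 4, 5 and 8 had 11.2, 17.6, 27.7 and 37.6 CPM. Stromal cells, which the Villin promoter does not target, held 58.2 ± 23.8 CPM of Spry2 in KO-labelled and 62.7 ± 26.6 CPM in WT-labelled mice (exact permutation p = 0.714). Lymphoid cells held 8.00 ± 2.54 and 16.5 ± 23.0 CPM (exact permutation p = 1). Colonocyte-like cells had 27.0 ± 24.3 CPM in KO-labelled and 22.9 ± 8.24 CPM in WT-labelled mice, and stem-like cells 51.7 ± 35.1 and 42.0 ± 10.7 CPM. Goblet-like cells had 27.8 ± 17.7 and 29.4 ± 10.0 CPM, deep crypt secretory-like cells 35.7 ± 27.0 and 38.1 ± 9.78, and cycling-like cells 16.3 ± 20.2 and 23.3 ± 8.69. Myeloid cells held 4 Spry2 UMIs and were not tested for it. In edgeR's quasi-likelihood test the epithelial log2 fold change was −0.12 ± 0.35 (95% confidence interval −0.90 to 0.66; adjusted p = 0.9999), the stromal one 0.01 and the lymphoid one −0.68. The lymphoid value was 0.64 without WT-labelled mouse 8, which had 50.99 CPM against 4.46 to 5.53 CPM in the other WT-labelled mice. Without mouse 7 the epithelial value was −0.61 ± 0.24 (adjusted p = 0.9999), and without mouse 8 the epithelial value was 0.07. The log2 ratio of epithelial to stromal Spry2 CPM within a mouse differed by −0.14 between the groups (exact permutation p = 0.8). On mm10 the gene lies on chromosome 14 from 105891947 to 105896819, on the minus strand, with 2 exons in GENCODE M21. The coding sequence, 105892806 to 105893750, and the 3′ untranslated region, 105891947 to 105892805, are in exon 2. The sources used here do not say which part is floxed, and 3′ tags outside the deleted part check nothing. The transcript counts go against the KO label or leave it unchecked. Every direction given here rests on the labels alone, and libraries are called KO-labelled throughout.

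**Figure D1:**
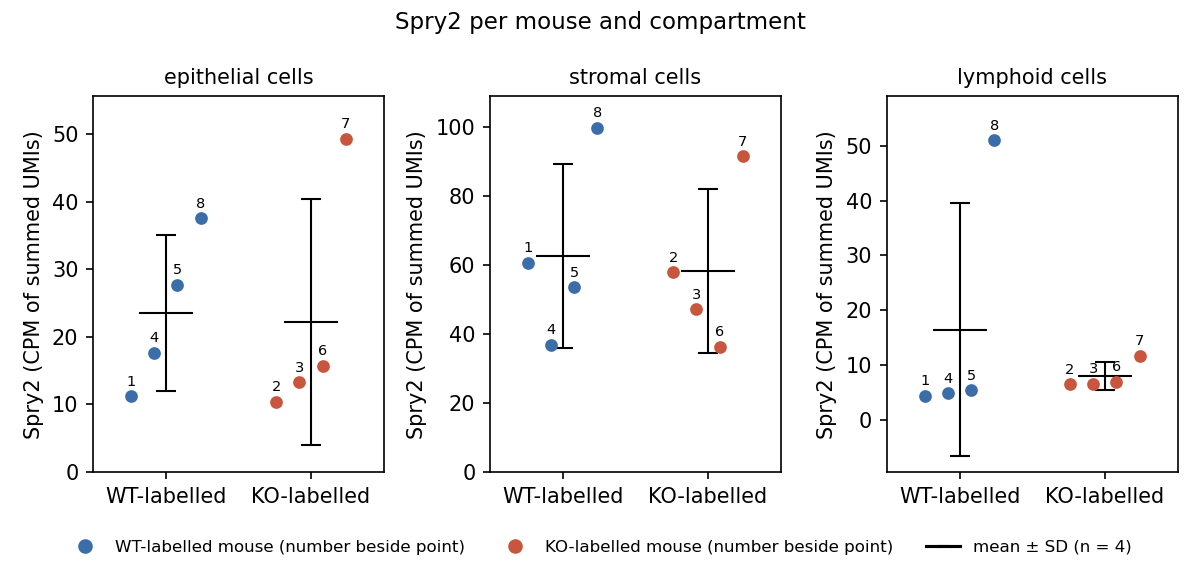
Spry2 in CPM of summed UMIs (y axis) for each mouse (points, numbered) in epithelial, stromal and lymphoid cells, by labelled genotype (x axis), with the mean and SD of 4 mice. In epithelial cells KO-labelled mouse 7 lies at 49.3 CPM and the other KO-labelled mice at 10.4 to 15.7 CPM, within and below the WT-labelled range.

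Among the classes named by the authors, fibroblasts, which build the connective tissue of the mucosa, made up 15.03 ± 3.97% of the cells of KO-labelled mice and 8.67 ± 4.37% of those of WT-labelled mice (SD, n = 4 each; exact permutation p = 0.0857, adjusted p = 0.686). CD90-positive fibroblasts without the authors' separate CD90-positive Igfbp3 subtype stood at 10.9 ± 2.74% against 4.98 ± 2.97% (exact permutation p = 0.0286, the smallest that 4 mice against 4 can give, adjusted p = 0.457), with WT-labelled mouse 8 at 0.636%. This separation rests on the denominator of all cells, of which KO-labelled mice 6 and 7 had 22.2% and 23.8% epithelial cells. As a share of non-epithelial cells the groups overlapped, with KO-labelled mouse 6 below WT-labelled mice 1, 4 and 5. The Igfbp3 subtype numbered 81, 104, 354 and 349 cells in KO-labelled mice 2, 3, 6 and 7. WT-labelled mice 1, 4, 5 and 8 had 15, 110, 490 and 164 of these cells. A share of both subtypes together was not tested. Epithelial cells made up 38.5 ± 18.0% in KO-labelled and 53.8 ± 17.4% in WT-labelled mice (exact permutation p = 0.257, adjusted p = 0.980). T cells, a class in which the authors place innate lymphoid cells, stood at 13.3 ± 8.25% and 7.90 ± 1.81% (exact permutation p = 0.371). B cells stood at 26.8 ± 4.30% and 24.7 ± 13.8% (exact permutation p = 0.8286) and macrophages at 1.38 ± 0.816% and 1.14 ± 1.35% (exact permutation p = 0.743). Group 2 innate lymphoid cells (ILC2), producers of type 2 cytokines, were 1.39 ± 1.36% and 0.668 ± 0.152% of cells (exact permutation p = 0.429). Regulatory T cells were 0.969 ± 0.653% and 0.650 ± 0.210% (exact permutation p = 0.457). None of the 8 classes or 16 subtypes tested with the exact permutation test passed an adjusted p of 0.05, and a single one with the smallest exact permutation p could not, since its adjusted p would be 0.229 and 0.457. In these samples dead cells had been removed with annexin V beads, a step that can set shares.

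The epithelial cells were compared by their share of 7 types, a test in which a single type with the smallest exact permutation p, 0.0286, would have an adjusted p of 0.2, so that it cannot show shares to be equal. Tuft-like cells, chemosensory cells marked by Dclk1 and Trpm5, made up 0.751 ± 0.554% of the clustered epithelial cells of KO-labelled mice and 1.81 ± 1.08% of those of WT-labelled mice (SD, n = 4 each; exact permutation p = 0.114, adjusted p = 0.8). Goblet-like cells, the mucus producers, made up 5.88 ± 3.25% and 6.86 ± 4.43% (exact permutation p = 0.629). Colonocyte-like cells, the absorptive cells, made up 47.6 ± 20.7% and 47.3 ± 14.1% (exact permutation p = 1). Cycling-like cells made up 8.63 ± 5.24% and 7.78 ± 2.62% (exact permutation p = 0.8), and stem-like cells, marked by Lgr5, 2.70 ± 0.437% and 3.68 ± 1.66% (exact permutation p = 0.314). Deep crypt secretory-like cells, marked by Reg4, made up 8.71 ± 4.11% and 9.44 ± 3.00% (exact permutation p = 0.8). Hormone-producing enteroendocrine-like cells made up 0.805 ± 0.311% and 0.931 ± 0.293% (exact permutation p = 0.571). Of all clustered epithelial cells, pooled over the mice of a label, unnamed clusters held 24.6% in KO-labelled and 21.8% in WT-labelled mice. Clusters led by markers of another lineage held 4.05% and 3.43% of the same pooled cells. The type shares above, which are means over mice, leave those other-lineage cells out of the denominator. Adjusted p-values over the 7 types were 0.8 or more, and the lowest under any alternative was 0.1, for tuft-like and stem-like cells without mouse 4.

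**Figure D2:**
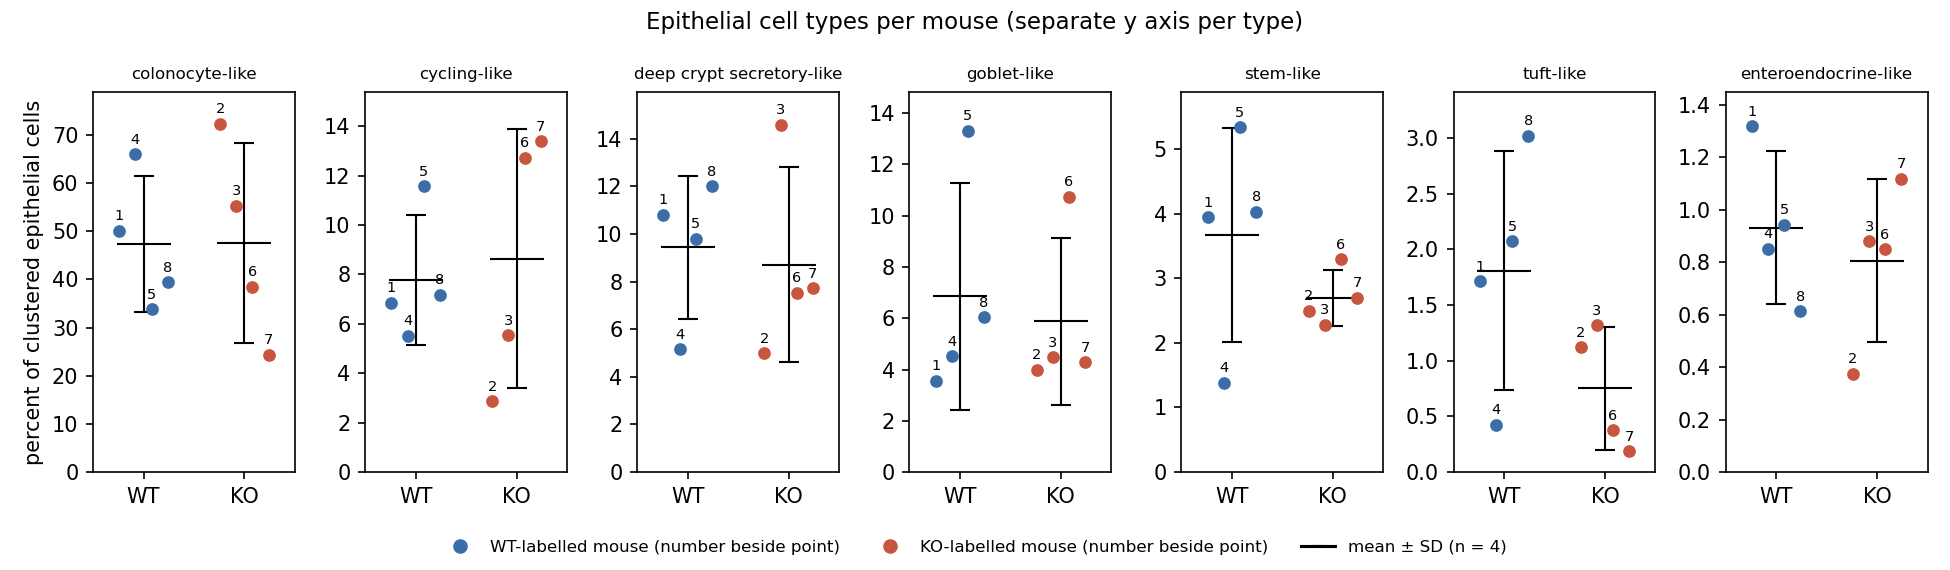
Share of each epithelial type (y axis, percent of clustered epithelial cells, a separate scale per type) in each mouse (numbered points) by labelled genotype (x axis), with the mean and SD of 4 mice. The groups overlap in every type; tuft-like cells average 0.751% in KO-labelled and 1.81% in WT-labelled mice.

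In the sums of all epithelial cells no gene passed the test, and the genes with the smallest p-values had moderate fold changes at low counts. Nov (Ccn3), a secreted matrix-associated protein of the CCN family, stood at 14.3 ± 6.70 CPM in KO-labelled and 39.1 ± 10.4 CPM in WT-labelled mice, a log2 fold change of −1.46 ± 0.33. Cma1, a chymase best known from mast cells, stood at 6.55 ± 2.27 against 2.07 ± 1.34 CPM (1.61 ± 0.43). St8sia5, a sialyltransferase, stood at 5.22 ± 1.42 against 2.29 ± 0.487 CPM (1.18 ± 0.27). Il33, an alarmin that activates type 2 immune cells, stood at 4.25 ± 2.63 against 1.40 ± 1.03 CPM (1.55 ± 0.57). In stromal cells Il33 was more abundant, at 149.9 ± 54.9 against 108.7 ± 68.4 CPM (0.44 ± 0.44). Further genes with higher values in KO-labelled mice were Adamts1, a secreted metalloprotease (1.66), Cd28, a co-stimulatory receptor of T cells (1.84), and Gk, glycerol kinase (0.53). Further genes with lower values were Nacad (−1.66), Disp2 (−1.21), the microtubule-associated ubiquitin ligase Mid1 (−0.90) and the cytochrome Cyp2c69 (−0.79), whose reads near-identical family members can share. Each of these genes had an adjusted p of 0.9999 in edgeR. With edgeR's quasi-likelihood test 0 of 11723 genes passed an adjusted p of 0.05, 96 had an unadjusted p under 0.05 and DESeq2 called 0. Chance alone gives 586 at that unadjusted p. The KO-labelled and WT-labelled values of 87 genes (0.742%) did not overlap, where chance gives 2.86%. In simulated data of this depth, with genes drawn independently, the same test recovered 32% of genes changed 2-fold and 86% of those changed 4-fold.

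Of the 22 gene lists tested in epithelial cells, 6 passed camera with the preset correlation and 0 with an estimated one. The tuft list was lower in KO-labelled mice, with 9 of 9 members below (median log2 fold change −0.43, adjusted p = 0.00319; adjusted p = 0.825 with an estimated correlation). Sh2d6 was at 7.87 against 12.3 CPM and Rgs13, a regulator of G protein signalling, at 7.18 against 10.6 CPM. The extracellular matrix list was higher, with 11 of 13 members above (0.38, adjusted p = 0.00319; adjusted p = 0.825 with an estimated correlation). Among its members Timp3, an inhibitor of metalloproteases, was at 54.3 against 36.8 CPM, and Sparc, a collagen-binding glycoprotein of stromal cells, at 19.2 against 11.4 CPM. The list of MAPK pathway feedback genes and targets was higher, with 10 of 16 members above (0.20, adjusted p = 0.0043; adjusted p = 0.825 with an estimated correlation). Spred2 and Spred1, relatives of the Sprouty proteins, measured 25.1 ± 0.841 against 20.9 ± 1.96 CPM (0.26 ± 0.12) and 18.1 against 14.6 CPM (0.31). The list of NF-kB targets and chemokines was higher in 12 of 13 members (0.24, adjusted p = 0.0188; adjusted p = 0.825 with an estimated correlation). The cytokine Il1b was at 5.71 against 1.61 CPM and the adhesion molecule Icam1 at 3.91 against 2.37 CPM. The proliferation list was lower in 13 of 16 members (−0.25, adjusted p = 0.0253; adjusted p = 0.825 with an estimated correlation). Mki67 was at 41.3 against 60.3 CPM but Pcna at 29.8 against 24.2 CPM. The enteroendocrine list was lower in 8 of 10 members (−0.35, adjusted p = 0.0251; adjusted p = 0.825 with an estimated correlation). The granule protein Chgb was at 24.4 against 52.7 CPM and the prohormone-processing enzyme Cpe at 3.83 against 5.61 CPM. No member of a list passed over all genes, and 0 did when adjusted over the list alone. Each of the calls was also lost without single mice. The MAPK list did not pass without mouse 1, 6 or 8 (adjusted p = 0.139, 0.311 and 0.0653), the tuft list without mouse 5, 6 or 7 (0.0756, 0.325 and 0.122) and the matrix list without mouse 3 or 8 (0.239 and 0.352). The NF-kB list did not pass without mouse 2, 5, 6 or 8 (adjusted p = 0.490, 0.0773, 0.0917 and 0.0782; median −0.07 without mouse 2), nor the proliferation list without mouse 2, 3 or 5 (0.920, 0.753 and 0.773; median 0.05 without mouse 5). The enteroendocrine list did not pass without mouse 1, 2, 3 or 5 (adjusted p = 0.498, 0.376, 0.239 and 0.306). The number of lists that passed was 3 without mouse 6. In cells under 50% mitochondrial UMIs outside the clusters led by markers of B cells, fibroblasts and T cells, an alternative chosen after seeing the data, 3 lists passed. The matrix, NF-kB and proliferation lists did not (adjusted p = 0.0846, 0.520 and 0.136). In the same cells with those clusters included, the NF-kB and proliferation lists did not pass (adjusted p = 0.0665 and 0.0629). The NF-kB median fell there to 0.10 from 0.24, while the proliferation median was −0.23 against −0.25. With an equal number of cells per type and mouse, the NF-kB and enteroendocrine lists did not pass (adjusted p = 0.855 for each), and the enteroendocrine median was 0.14. That sum held only 3 enteroendocrine-like and 2 tuft-like cells per mouse. It also left out cells of 50% or more mitochondrial UMIs and the clusters led by other lineages, so it does not isolate the effect of type shares.

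The other 16 lists tested in epithelial cells did not pass. The goblet list had 8 of 10 members lower (median −0.18, adjusted p = 0.203), with the mucin Muc2 at 1221 ± 634.7 against 1572 ± 397.4 CPM and the secreted peptide Spink4 at 1256 against 2126 CPM. The colonocyte list had 9 of 12 members lower (−0.12, adjusted p = 0.203), with the carbonic anhydrase Car1 at 692 against 1130.0 CPM and the sugar-phosphate exchanger Slc37a2 at 128 against 98.6 CPM. The interferon list had 8 of 10 members higher (0.06, adjusted p = 0.620), with the antiviral gene Ifit1 at 9.55 against 4.62 CPM. The type 2 epithelial axis, which holds Il33, had 4 of 7 members lower (−0.02, adjusted p = 0.581); its member Retnlb, a goblet cell product of type 2 responses, was at 215 ± 289.5 against 555 ± 563 CPM. The list of ERBB ligands and receptors (adjusted p = 0.973; the test pointed higher, median −0.02 and mean −0.01) held the ligand Tgfa at 11.4 against 12.6 CPM and the receptor Erbb3 at 114 against 102 CPM. FoxO targets (0.11, adjusted p = 0.266) held Klf2 at 71.1 against 59.8 CPM and Ccng2 at 187 against 149 CPM. Wnt targets (adjusted p = 0.907; the test pointed lower while median and mean were 0.02) held Cd44 and Axin2 at −0.33 and −0.28 log2. The list of the Notch pathway and lineage factors (adjusted p = 0.973) held Hes1 and Jag1 at −0.16 and −0.12. In the MHC class II list (adjusted p = 0.203; test higher, median −0.04 and mean −0.06) H2-DMb1 and H2-DMa were at −0.30 and −0.17. In the antimicrobial list (adjusted p = 0.973; test lower, median 0.26 and mean 0.28) Wfdc2 and Nos2 were at 0.30 and 0.94. The tight junction list had 12 of 14 members higher (0.09, adjusted p = 0.233), with the claudins Cldn8 at 0.43 and Cldn15 at −0.71. Ion and water transport (−0.10, adjusted p = 0.408) held the water channel Aqp4 at −0.62 and the sodium channel subunit Scnn1g at 0.39. The unfolded protein response (−0.10, adjusted p = 0.233) held Creld2 and Pdia6 at −0.23 and −0.15. The list of lipid and bile acid nuclear receptor genes (−0.14, adjusted p = 0.203) held the fatty acid binding protein Fabp2 at −0.43. Immediate early and dissociation stress genes (0.01, adjusted p = 0.233) held Socs3 at 0.87 and Nr4a1 at 0.30. All 13 mitochondrially encoded genes had higher values (0.17, adjusted p = 0.907), with mt-Nd6 at 0.36 and mt-Nd2 at 0.26. The lists of type 2 immune cytokines and of stromal niche factors had fewer than 5 tested members here; Areg and Il17rb stood at −0.16 and −0.02, and Bmp2 and Ptges at 0.38 and −0.43. All of these single genes had an adjusted p of 0.9999 in edgeR.

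**Figure D3:**
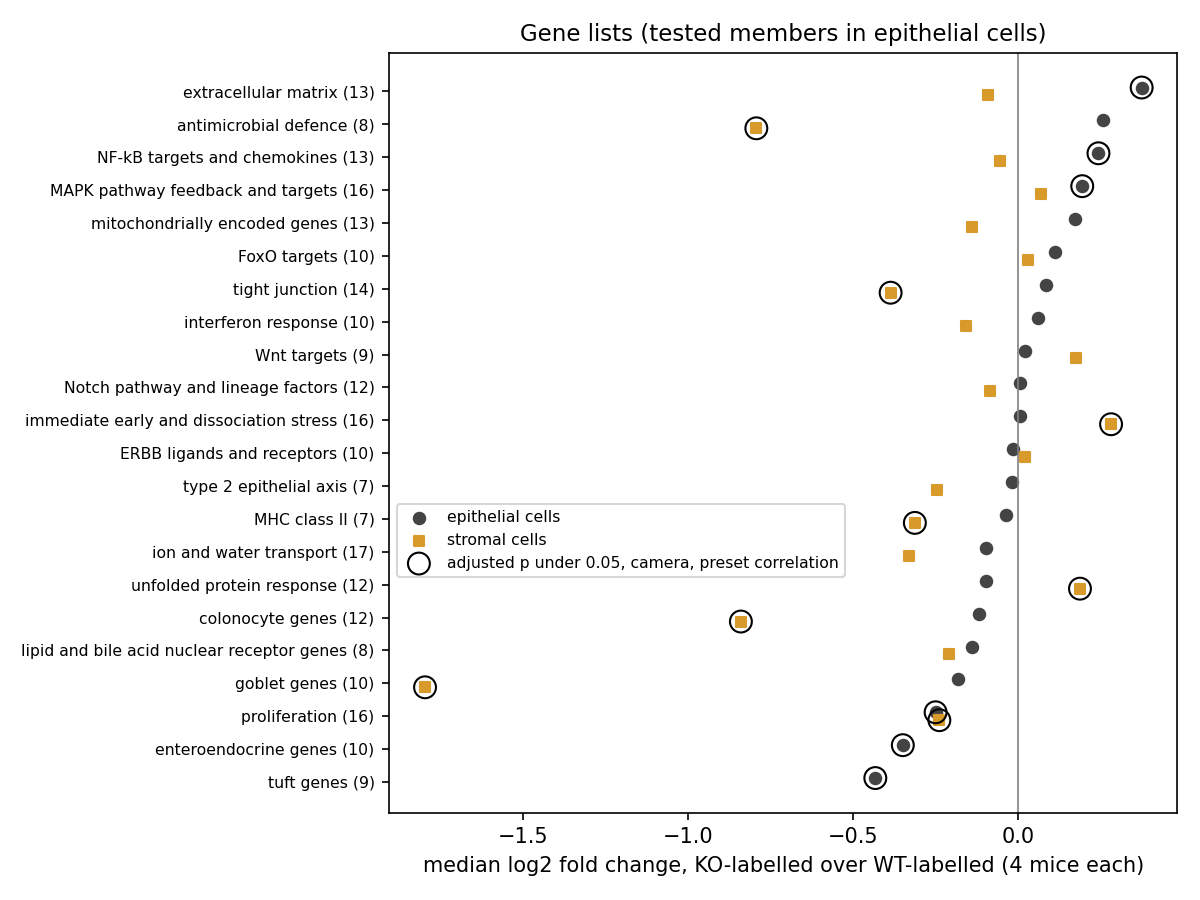
Median log2 fold change, KO-labelled over WT-labelled mice (x axis, 4 mice each), of the genes of each list (y axis, with the number tested in epithelial cells) in epithelial cells (circles) and stromal cells (squares); rings mark an adjusted p under 0.05 by camera with the preset correlation. The goblet list lies at −0.18 in epithelial and −1.80 in stromal cells; no ring holds with an estimated correlation.

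In cycling-like cells, the dividing cells of the crypt, Nov fell by 3.66 ± 0.57 on the log2 scale, from 104 ± 58.1 CPM in WT-labelled to 4.96 ± 6.99 CPM in KO-labelled mice, with all 4 KO-labelled mice below all 4 WT-labelled mice (edgeR adjusted p = 0.0272). Products of secretory cells followed it in the ranking without passing in edgeR. Clca1, a protein secreted by goblet cells, stood at 41.2 ± 41.4 against 3929 ± 4899 CPM (−7.16 ± 1.26, adjusted p = 0.0592), and Fcgbp, a mucus protein, at 112 against 1686 CPM (−3.93, adjusted p = 0.470). The pentraxin Mptx1, which has near-identical relatives, stood at 1748 against 17800.0 CPM (−3.35, adjusted p = 0.470), and Sytl2, a vesicle transport protein, at 9.88 against 30.1 CPM (−1.89). The highest-ranked genes with higher values were Tipin and Asf1b, which act at the replication fork, at 1.21 and 1.08, Cdca7l at 1.10, Tprkb at 1.11 and Kxd1 at 0.70 (adjusted p = 0.643 each). Of these cells, cluster 21, which has Retnlb and Ang4 beside cell cycle genes among its 10 leading genes, held 80 WT-labelled and 10 KO-labelled cells, and the largest share came from cluster 14 in WT-labelled mice (220 cells) and from cluster 10 in KO-labelled mice (278 cells). Without cluster 21, an alternative chosen after seeing the data, Nov was at −1.15 ± 0.59 (edgeR adjusted p = 0.632) and below the expression filter, with 10 KO-labelled and 51 WT-labelled UMIs left of 16 and 565. The goblet list was lower in 9 of 10 members (median −0.92, adjusted p = 0.0004, 3 members passing when adjusted over the list alone; adjusted p = 0.467 with an estimated correlation). The unfolded protein response list was lower in 12 of 12 members (−0.60, adjusted p = 3.69e-05, 5 members passing when adjusted over the list alone; adjusted p = 0.352 with an estimated correlation). The stress transcription factor Ddit3 was at 18.8 against 49.0 CPM and Herpud1 at 121 against 219.5 CPM. Cluster 21, mostly WT-labelled, had 7 of 10 goblet markers up. Neither of these 2 lists was tested without it, so a change within dividing cells cannot be told apart from fewer cells of that cluster. All 13 mitochondrially encoded genes were lower (−0.49, adjusted p = 0.000227, 1 member passing when adjusted over the list alone; adjusted p = 0.467 with an estimated correlation). Cluster 10, with 278 KO-labelled and 204 WT-labelled cells, had a median of 0.270% mitochondrial UMIs and 1413.5 UMIs per cell, and cluster 14, with 77 and 220, 14.97% and 10746 UMIs. The gene mt-Atp8 was at 336 against 685 CPM and mt-Nd4l at 668 against 1123 CPM. The proliferation list, whose genes largely define these cells, was higher in 14 of 16 members (0.19, adjusted p = 0.0188, 0 passing when adjusted over the list alone; adjusted p = 0.467 with an estimated correlation). Stmn1 was at 993 against 673 CPM and Mcm2 at 35.2 against 21.1 CPM. Of the Wnt targets, a list that did not pass (adjusted p = 0.363), 1 gene passed when adjusted over the list alone: Cd44, named after its values were seen, with a log2 fold change of −1.12. By edgeR 1 gene of 7252 passed and 485 had an unadjusted p under 0.05, where chance gives 363. The values of the 2 groups did not overlap in 293 genes (4.04%), where chance gives 2.86%. DESeq2 called 1 other gene, Clca1 (−6.62, adjusted p = 0.0390), and gave Nov an adjusted p of 0.360. Nov did not pass without mouse 1, 2, 7 or 8 (edgeR adjusted p = 0.164, 0.142, 0.135 and 0.0771). Its log2 fold change stayed at −3.55, −3.60, −3.12 and −3.22 in these fits. When mouse 3, 4 or 5 was left out, 7, 8 and 2 genes passed. The proliferation list did not pass without mouse 2, 4 or 7 (adjusted p = 0.0746, 0.1597 and 0.127) nor the mitochondrial list without mouse 7 (0.0539); 2 lists passed without mouse 7.

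In deep crypt secretory-like cells, which lie beside the stem cells of the colonic crypt, Nov led the genes with lower values, as in the epithelial sums and cycling-like cells, and Cma1 those with higher values. Nov stood at 102 ± 30.7 CPM in KO-labelled and 325 ± 152 CPM in WT-labelled mice (−1.67 ± 0.29) and Cma1 at 78.6 ± 30.3 against 21.9 ± 4.68 CPM (1.73 ± 0.30), with no overlap between the groups for either gene. Both had an adjusted p of 0.0776 in edgeR and passed in DESeq2 (adjusted p = 0.000289 for Nov and 0.00132 for Cma1). Further higher values were those of the myelin protein gene Pmp22 (0.97), the claudin Cldn8 (1.17), the stress gene Gadd45a (0.80) and Gna13 (0.66), and further lower values those of the lipid phosphatase Plpp1 (−0.65), Smim27 (−0.98), the homeobox gene Hoxa7 (−0.86) and the sterol demethylase Cyp51 (−0.64), all with an adjusted p of 0.9995. By edgeR 0 of 5948 genes passed and 146 had an unadjusted p under 0.05, and DESeq2 called 2. No gene list passed (0 of 14), and 1 gene, Cldn8, passed when adjusted over the list alone, in the tight junction list. Without single mice, 2 lists passed without mouse 1, 5, 7 or 8, 1 without mouse 3 and 3 without mouse 4. Without mouse 5, Nov passed in edgeR (−1.83, adjusted p = 0.0227) together with Iglc1 (−1.99, adjusted p = 0.0227). Without mouse 7, Nov (−1.91, adjusted p = 0.0419) and Cma1 (1.98, adjusted p = 0.00332) did.

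**Figure D4:**
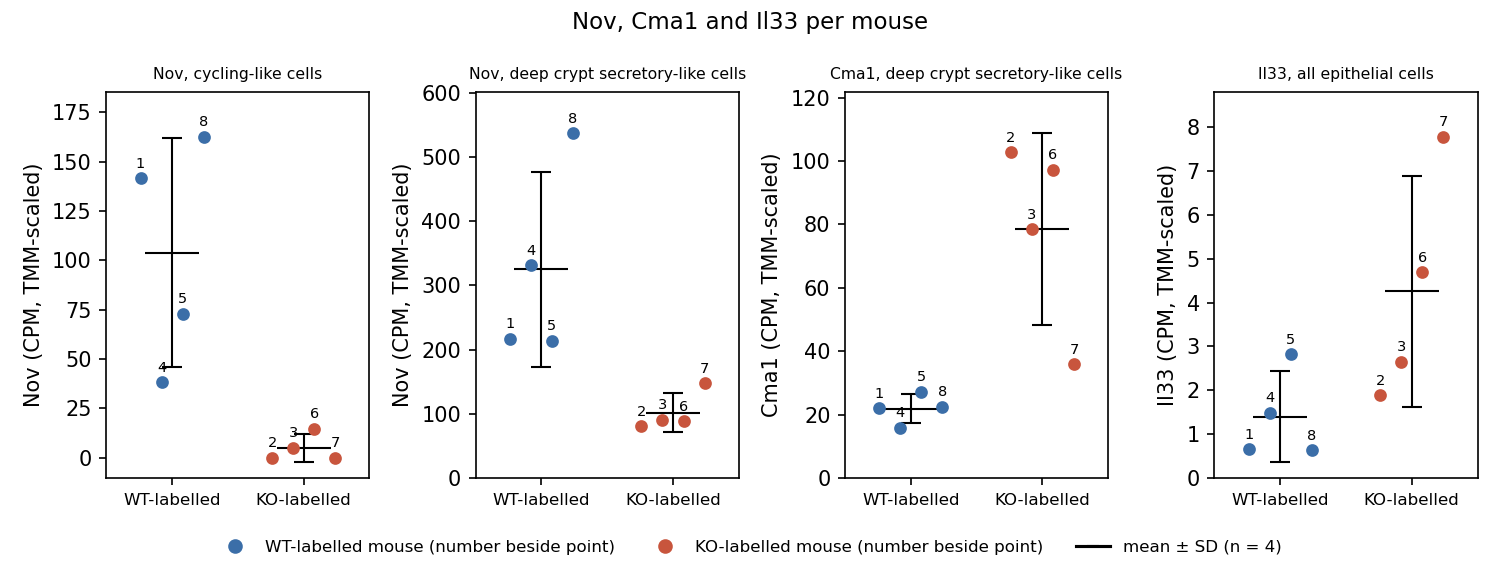
TMM-scaled CPM (y axis) of Nov in cycling-like and deep crypt secretory-like cells, Cma1 in deep crypt secretory-like cells and Il33 in all epithelial cells, per mouse (numbered points) and labelled genotype (x axis), with the mean and SD of 4 mice. Nov averages 4.96 CPM in KO-labelled and 104 CPM in WT-labelled cycling-like cells, and for Il33 the groups overlap.

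In colonocyte-like cells the MAPK list was higher in 7 of 9 members (median 0.44, adjusted p = 0.00644; adjusted p = 0.342 with an estimated correlation). Dusp5, a phosphatase that inactivates ERK, was at 72.2 ± 14.5 against 49.4 ± 4.25 CPM (0.53 ± 0.16), and Spred2 at 35.6 against 24.9 CPM (0.50). FoxO targets were higher in 6 of 7 members (0.35, adjusted p = 0.0141; adjusted p = 0.342 with an estimated correlation), among them the cyclin Ccng2 at 451 against 326 CPM and the insulin receptor Insr at 83.3 against 64.3 CPM. Tight junction genes were higher in 10 of 13 members (0.22, adjusted p = 0.00644; adjusted p = 0.342 with an estimated correlation), among them occludin, Ocln, at 172 against 121 CPM. Mitochondrially encoded genes were higher in 11 of 13 members (0.17, adjusted p = 0.0180; adjusted p = 0.604 with an estimated correlation), with mt-Nd6 at 133 against 98.9 CPM and mt-Nd2 at 4679 against 3681 CPM. Of the colonocyte-like cells, cluster 11, with a median of 10540.5 UMIs per cell, held 61 KO-labelled and 395 WT-labelled cells, 294 from mouse 8 and 0 from mouse 7. The authors had named 324 cells of cluster 11 stem-progenitor and 22 enterocyte. No member of these 4 lists passed over all genes, and 0 did when adjusted over the list alone. Among single genes, the hair follicle protein gene Tchh (1.65), the pyruvate dehydrogenase phosphatase Pdp1 (0.66), Sned1 (0.89), the metalloprotease Adamts9 (1.68) and Gngt2 (0.91) led the higher values. The glutathione transferase Gstm2 (−1.05), Mecr (−1.08), the mitochondrial protein C1qbp (−1.25), Ccdc91 (−0.74) and Rpsa (−0.63), which has many pseudogenes, led the lower ones. All had an edgeR adjusted p of 0.961. By edgeR 0 of 8217 genes passed and 326 had an unadjusted p under 0.05; DESeq2 called 0. The MAPK call was lost without mouse 1, 5 or 6 (adjusted p = 0.134, 0.0533 and 0.0968), the tight junction call without mouse 2 (0.0584) and the mitochondrial call without mouse 2, 3 or 8 (0.199, 0.141 and 0.822; median −0.0007 without mouse 8).

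In goblet-like cells the tight junction list was higher in 10 of 11 members (median 0.42, adjusted p = 0.0404; adjusted p = 0.787 with an estimated correlation), with the claudins Cldn4 at 757 against 251 CPM and Cldn23 at 148 against 84.1 CPM. The goblet-like cells came from cluster 9 (205 KO-labelled and 288 WT-labelled cells) and cluster 18 (38 and 174), in which mouse 8 had 103 cells, mouse 6 had 3 and mouse 7 had 0, and whose leading genes include Retnlb, Ang4, Muc2, Nov and Mptx1. The authors had named 167 cells of cluster 18 secretory-progenitor and 0 goblet. In this list 0 members passed over all genes and 0 when adjusted over the list alone. Of the antimicrobial list, which did not pass (adjusted p = 0.292), 1 gene passed when adjusted over the list alone, Duoxa2. Higher values were those of the stem cell antigen Ly6a (1.52), Duoxa2, the maturation factor of an epithelial hydrogen peroxide producer (2.17), Rsbn1 (1.11), Nbeal2 (0.98) and the cell cycle inhibitor Cdkn2b (1.33). Lower values were those of the mitochondrial enzymes Acat1 (−1.39) and Ndufs3 (−1.01), the water channel Aqp4 (−2.23), Thoc7 (−0.88) and Csrp2 (−1.36), all with an edgeR adjusted p of 0.846. In stem-like cells the same gene, Cldn4, stood at 299.7 ± 55.1 against 106 ± 64.1 CPM (1.41 ± 0.34) and passed when adjusted over the list alone, 1 of the 10 tested genes of a list that did not pass (adjusted p = 0.352). B4galt6 (1.01), Tvp23b (0.90), Rgcc (0.96) and transthyretin, Ttr (1.17), were also higher in value. Lower values in stem-like cells were those of Mptx1 (−2.85), Sprr2a3 (−1.79) and Gsdmc4 (−1.23), which belong to families of near-identical genes, and of the intestinal transcription factor Cdx2 (−1.25), all with an edgeR adjusted p of 0.999. By edgeR 0 of 4185 genes passed in goblet-like and 0 of 2731 in stem-like cells, 175 and 81 had an unadjusted p under 0.05, and DESeq2 called 0 in either. Without mouse 5, Mptx1 passed in stem-like cells (−3.24, adjusted p = 0.0158), and with sex and mouse number as terms, chosen after seeing the data, Cldn4 did (1.78, adjusted p = 0.00812). The tight junction list of goblet-like cells did not pass without mouse 2, 4, 6, 7 or 8 (adjusted p = 0.171, 0.114, 0.2398, 0.0697 and 0.253), nor with sex, mouse number or both as terms (0.0527, 0.0554 and 0.0681). Its median was 0.49, 0.48, 0.09, 0.45 and 0.25 without these mice and 0.42, 0.43 and 0.47 with these terms. Only without mouse 6 or 8 was the median smaller than with all mice. In goblet-like cells 3 lists passed without mouse 1 or 5 and 4 without mouse 3. None of 6 lists passed in stem-like cells; 1 did without mouse 1, 2 or 8, 2 without mouse 5, 3 without mouse 3 and 4 without mouse 4. Tuft-like and enteroendocrine-like cells were too few per mouse for a test of genes.

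In stromal cells, genes of the epithelium had lower values in the KO-labelled mice. The goblet list was lower in 8 of 8 members (median −1.80, adjusted p = 1.06e-09, 5 members passing when adjusted over the list alone; adjusted p = 0.109 with an estimated correlation). Without the 28 stromal cells of 10 or more UMIs of goblet genes, an alternative chosen after seeing the data, the median over 7 tested members was −0.98 (adjusted p = 1.17e-06, 0 members passing when adjusted over the list alone; adjusted p = 0.210 with an estimated correlation). In WT-labelled mice 5 and 8 such cells held 1441 of 2478 and 405 of 563 of the UMIs of these genes. Fcgbp was at 4.66 ± 3.05 against 40.5 ± 44.1 CPM (−2.87 ± 0.71) and the trefoil peptide Tff3 at 15.7 against 47.5 CPM (−1.71). The colonocyte list was lower in 12 of 12 members (−0.84, adjusted p = 2.27e-09; adjusted p = 0.109 with an estimated correlation). Lypd8, which keeps bacteria off the epithelium, was at 57.9 against 112 CPM and Muc3 at 11.4 against 23.5 CPM. Antimicrobial genes were lower in 7 of 7 members (−0.79, adjusted p = 3.36e-05; adjusted p = 0.132 with an estimated correlation), with the immunoglobulin transporter Pigr at 22.9 against 54.1 CPM. Tight junction genes were lower in 7 of 8 (−0.39, adjusted p = 0.00328; adjusted p = 0.109 with an estimated correlation), with Cldn7 at 9.63 against 24.8 CPM and Tjp3 at 1.33 against 3.75 CPM. The epithelial genes Sval1 (−1.52), Krt19 (−1.04) and Klk1 (−1.76) were among the other lower genes of smallest p. Proliferation genes were lower in 5 of 6 members (−0.24, adjusted p = 0.00825; adjusted p = 0.109 with an estimated correlation). Mcm3 was at 5.48 against 7.37 CPM and Mcm2 at 4.19 against 5.37 CPM. MHC class II genes were lower in 6 of 6 (−0.31, adjusted p = 0.0293; adjusted p = 0.424 with an estimated correlation), with H2-Eb1 at 18.9 against 25.8 CPM and H2-Aa at 19.9 against 24.3 CPM. Immediate early and dissociation stress genes were higher in 12 of 16 members (0.28, adjusted p = 6.44e-05; adjusted p = 0.190 with an estimated correlation), with Nr4a1 at 561 against 314 CPM and Junb at 3248 against 2490.0 CPM. The unfolded protein response list was higher in 12 of 12 members (0.19, adjusted p = 0.0182; adjusted p = 0.424 with an estimated correlation), with Atf4 at 473 against 369 CPM and the chaperone Hyou1 at 35.7 against 26.7 CPM. Apart from the 5 goblet genes, 0 members of these lists passed when adjusted over the list alone, and 0 passed over all genes. Stromal niche factors did not pass (adjusted p = 0.508; the test pointed higher, median 0.06 and mean −0.06). Higher single values were those of the small GTPase regulator Rp2 (0.43), Megf9 (0.58), Cdk2ap2 (0.43), Zfp954 (0.66) and the lipid kinase Pi4kb (0.59). By edgeR 0 of 11564 genes passed and 227 had an unadjusted p under 0.05; DESeq2 called 1, Fcgbp (−3.08, adjusted p = 0.0205), against an adjusted p of 0.9998 in edgeR. The proliferation call was lost without mouse 1 (adjusted p = 0.0805), the MHC class II call without mouse 2, 3, 4, 5 or 8 (0.123, 0.499, 0.136, 0.0553 and 0.0567) and the unfolded protein response call without mouse 1, 3 or 6 (0.324, 0.405 and 0.0562).

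In lymphoid cells, all 16 genes of the proliferation list had lower values in the KO-labelled mice (median −0.37, adjusted p = 8.59e-10; adjusted p = 0.820 with an estimated correlation). These sums mix subtypes of the authors: B progenitors numbered 26, 19, 31 and 1 in KO-labelled mice 2, 3, 6 and 7 and 124, 68, 59 and 0 in WT-labelled mice 1, 4, 5 and 8 (exact permutation p = 0.2 for their share). In tests of subtypes, added after seeing the data, the list was lower in 8 of 9 members in mature B cells (−0.33, adjusted p = 3.88e-05, 1 member passing when adjusted over the list alone; adjusted p = 0.167 with an estimated correlation). It was lower in 14 of 16 in plasma cells (−0.23, adjusted p = 4.80e-05; adjusted p = 0.498 with an estimated correlation) and did not pass in T and innate lymphoid cells (0.10, adjusted p = 0.366). The replication factor Mcm2 was at 18.4 ± 2.72 against 24.2 ± 4.64 CPM (−0.40 ± 0.17) and the topoisomerase Top2a at 45.5 against 63.1 CPM (−0.46). Goblet genes, which are products of epithelial cells, were lower in 9 of 9 members (−0.57, adjusted p = 8.26e-05; adjusted p = 0.820 with an estimated correlation), with Fcgbp at 12.1 against 25.98 CPM and Muc2 at 24.4 against 44.0 CPM. Ion and water transport genes were lower in 9 of 11 members (−0.19, adjusted p = 0.0168; adjusted p = 0.841 with an estimated correlation), with Slc12a2 at 6.96 against 10.4 CPM and Kcne3 at 1.94 against 4.20 CPM. Type 2 immune cytokines and receptors did not pass (adjusted p = 0.953; the test pointed lower, median 0.25 and mean 0.23). Mid1 stood at 5.79 ± 2.34 against 17.6 ± 7.39 CPM (−1.57 ± 0.37). The mitotic kinase Plk1 (−1.22), the nuclease Dna2 (−1.14), Anapc13, a subunit of the anaphase-promoting complex (−0.49), and Atp5k (−0.50) were the other lower genes of smallest p. Higher values were those of Zfp281 (0.46), the iron transporter Slc11a2 (0.58), Hdhd5 (0.57), Bag4 (0.35) and the MAPK phosphatase Dusp10 (0.75). By edgeR 0 of 11397 genes passed, 108 had an unadjusted p under 0.05 and DESeq2 called 0; no list member passed in the lymphoid sums when adjusted over the list alone. The goblet call was lost without mouse 4 or 7 (adjusted p = 0.0606 and 0.0617) and the ion transport call without mouse 4, 6 or 7 (0.606, 0.261 and 0.270; median 0.05 without mouse 4 and 0.01 without mouse 6). The number of lists that passed in lymphoid cells was 5 without mouse 1 or 3, 6 without mouse 2, 1 without mouse 4 and 9 without mouse 8.

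In myeloid cells, most of which were macrophages, the lower genes of smallest p were Iglc1 and Ly6d, neither of which passed in edgeR. Iglc1, an immunoglobulin light chain gene with near-identical relatives, stood at 32.1 ± 21.5 CPM in KO-labelled and 20580.0 ± 28790.0 CPM in WT-labelled mice (−9.27 ± 1.81, edgeR adjusted p = 0.442), and Ly6d, a marker of early B cells and plasmacytoid dendritic cells, at 40.8 against 268 CPM (−2.88, adjusted p = 0.442). Iglc1 was at 61140 and 21040 CPM in WT-labelled mice 1 and 4 and at 88.7 and 58.0 CPM in mice 5 and 8, near the highest KO-labelled value of 57.2 CPM. WT-labelled mice 1, 4 and 5 had 1, 1 and 9 macrophages with 10 or more UMIs of the antibody gene Jchain. In macrophages, where Iglc1 passed, edgeR called 0 genes without those cells, an alternative chosen after seeing the data. The myeloid sums were not tested without them. Hypk (−1.02), Rtl8a (−0.87) and the RNA polymerase subunit Polr2l (−1.04) followed. Higher values were those of the small GTPase Rrad (1.16), Rgcc (1.05), the unnamed gene model AI839979 (1.68), the dendritic cell lectin Cd209a (0.97) and Ms4a4c (1.11). By edgeR 0 of 4832 genes passed and 121 had an unadjusted p under 0.05. DESeq2 called 1, Iglc1 (−9.31, adjusted p = 0.000105). Of 9 lists 0 passed, the unfolded protein response coming closest (median −0.23, adjusted p = 0.0906). Mouse 8 contributed 9 and mouse 1 35 of the myeloid cells. Without mouse 5, Iglc1 passed in edgeR (−9.67, adjusted p = 0.0323), without mouse 7 the fibroblast genes Col3a1, Col1a2 and Dcn did (−4.35, −4.93 and −4.67), and 1 list passed without mouse 1, 3 or 8.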

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

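Chosen after the result was seen were the tests of the Spry2 pattern, the test without stromal cells of 10 or more UMIs of goblet genes, and the settings that added terms or left out cells. A sample was marked when its gap to the nearest of the other 3 samples of its group, over the whole range, passed Dixon's limit; this marked 25 of 398 groups of 4 samples, and chance marks about 1 in 20. Of 8 groups of Spry2 values it marked 5, of which 2 could not have been otherwise once 3 of their values were 0, of 12 of quality measures 1, of 30 of shares 1 and of 348 of named genes 18. Of 6 differences between epithelial and stromal effects tested, 1 had an exact permutation p of 0.0286.

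Spry2 stood apart in epithelial cells of KO-labelled mouse 7, with 49.3 CPM against 10.4 to 15.7 CPM in the other KO-labelled mice. It was at 11.8 CPM in lymphoid cells of mouse 7 (others 6.52 to 7.03), at 50.99 CPM in lymphoid cells of WT-labelled mouse 8 (others 4.46 to 5.53), and at 4.87 and 2.33 CPM in the myeloid cells of mouse 7 and of WT-labelled mouse 4, where the others had 0. These last 2 marks carry no information, since with 3 values at 0 any count is marked, and they rest on 3 UMIs and 1 UMI. RNA of stromal cells as the whole source of epithelial Spry2 is argued against: the lowest epithelial over stromal ratio of Spry2 in a KO-labelled mouse was 0.179, and the highest such ratio of a fibroblast marker gene was 0.00597. A wrong label of mouse 7 stays open, since without it the log2 fold change was −0.61 ± 0.24 (unadjusted p = 0.0303), which neither reaches a loss of the transcript nor excludes a partial one. Mouse 7 was also the highest KO-labelled mouse in stromal cells, which the Villin promoter does not target, at 91.4 CPM (others 36.3 to 57.9). Its epithelial over stromal ratio of Spry2 was 0.539, against 0.179 to 0.433 in the other KO-labelled and 0.185 to 0.519 in the WT-labelled mice. The epithelial CPM in this ratio counts mitochondrial UMIs, whose share differed between mice. In the epithelial cells kept for clustering, Spry2 was at 51.8 CPM in mouse 7. WT-labelled mice 4 and 5 had 21.5 and 32.4 CPM there, and 36.9 and 53.4 CPM in stromal cells. By these values the ratio of mouse 7 was below those of mice 4 and 5 and above those of mice 1 and 8. The ratio thus does not set mouse 7 apart from the WT-labelled mice. A deletion that leaves the 3′ part of the transcript in place may be the biological explanation; it was not tested, because the floxed part is not given in the sources used here.

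Goblet genes differed between compartments: the KO-labelled effect on the log2 of their summed CPM (pseudocount 0.5) was −0.25 in epithelial and −2.27 in stromal cells, a difference of 2.03 (exact permutation p = 0.0286, the smallest possible). The most abundant genes of the list weigh most in such a sum. Droplets that hold a stromal and a goblet cell may contribute: 28 stromal cells had 10 or more UMIs of goblet genes, and in WT-labelled mice 5 and 8 such cells held 1441 of 2478 and 405 of 563 of those UMIs. Without them the median log2 fold change was −0.98 (adjusted p = 1.17e-06 with the preset and 0.210 with an estimated correlation). With each mouse's epithelial share as a term, a test for free RNA, it was −1.47 (adjusted p = 2.74e-09 and 0.137); this met the bound set in advance against free RNA, but that bound relied on the preset correlation, and with an estimated one the list did not pass before (0.109) or after, so the median was not beyond its spread. The lower values were not particular to stromal cells or to goblet genes. Goblet genes were also lower in lymphoid cells, and colonocyte and tight junction genes were lower in stromal cells. None of these lists passed with an estimated correlation. Both explanations stay open, and so does a change in stromal cells themselves, which was not tested.

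Nov fell in cycling-like cells by 3.66 ± 0.57 on the log2 scale, with 16 UMIs in KO-labelled and 565 in WT-labelled mice. Fewer secretory cells among these cells in KO-labelled mice may be the source: cluster 21, whose 10 leading genes are Retnlb, Ang4 and otherwise cell cycle genes, held 10 KO-labelled and 80 WT-labelled cells. Without it the value was −1.15 ± 0.59 (unadjusted p = 0.0647, adjusted p = 0.632), with 10 and 51 UMIs left. The call ended because the fold change shrank at about the same SE; most Nov UMIs were in that cluster, and the gene was also below the expression filter without it. With so few UMIs left the test decides neither way on the remaining fall. A lower Nov level within the secretory cells stays open. In deep crypt secretory-like cells the log2 fold change was −1.67 ± 0.29 (edgeR adjusted p = 0.0776). In goblet-like cells it was −0.98 ± 0.79 (172 ± 189 against 343 ± 222 CPM, edgeR adjusted p = 0.852), and the groups overlapped.

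The other samples that stood apart follow as values. KO-labelled mouse 6 had 28.2 M UMIs (others 19.0 to 20.2 M) and a goblet-like share of 10.7% (others 4.00 to 4.48%). In epithelial cells Cyp2c69 was at 11.4 CPM in mouse 6 (others of its group 6.44 to 7.06) and at 20.96 CPM in mouse 8 (others 10.9 to 11.9). Pcna was at 19.4 CPM in mouse 3 (others 32.3 to 34.6) and Nos2 at 17.1 CPM in mouse 2 (others 0.402 to 3.07). Aqp4 was at 538 CPM in mouse 8 (others 237 to 262) and Fabp2 at 336 CPM in mouse 8 (others 133 to 158). In stromal cells Cdk2ap2 was at 92.8 CPM in mouse 2 (others 110.7 to 112), Sval1 at 8.02 CPM in mouse 1 (others 17.4 to 18.5) and Fcgbp at 106 CPM in mouse 8 (others 12.7 to 26.4). In stromal cells of mouse 3, Krt19 was at 30.75 CPM (others 17.2 to 18.7), Klk1 at 8.73 CPM (others 2.98 to 3.50) and Tjp3 at 3.12 CPM (others 0.541 to 0.929). Mcm2 was at 31.05 CPM in lymphoid cells of mouse 1 (others 21.05 to 22.7). In cycling-like cells Kxd1 was at 45.1 CPM in mouse 1 (others 66.7 to 70.0) and Mptx1 at 5594 CPM in mouse 3 (others 243 to 835). Insr was at 51.6 CPM in colonocyte-like cells of mouse 8 (others 67.7 to 69.2), and Rsbn1 at 57.8 CPM in goblet-like cells of mouse 2 (others 34.3 to 37.1). Nov was at 147 CPM in deep crypt secretory-like cells of mouse 7 (others 80.8 to 90.6).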

How the results depend on the processing

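Settings chosen after the result was seen were the added terms (sex, mouse number, both), the epithelial cell filters, macrophages without cells of 10 or more Jchain UMIs, and shares of non-epithelial cells. No paired analysis was possible because the groups share no mouse number. Over all settings, 292 values of the main results stayed (on their side of the threshold and in direction, or, for counts of genes and lists, within 1.5 times the count with all mice), 81 moved and 7 reversed. Of single genes 2563 values stayed, 37 newly passed, 7 no longer passed and 19 reversed; of single lists 251 stayed, 105 no longer passed and 7 reversed; of shares 164 stayed and 23 reversed. The cause was not tested except where one is given. With the exact permutation test a single share of smallest p would have an adjusted p of 0.2 or more. Its side of the threshold was thus nearly fixed in advance, as were the counts of passing shares among the main results. Many single genes also started far from the threshold, so for these values staying mainly means an unchanged direction. The setting of 50 cells per mouse ran for colonocyte-, cycling- and deep crypt secretory-like cells alone, since fewer than 3 mice of a group had 50 cells of the other types. In the simulated data, with genes drawn independently, 2-fold changes were recovered in 12% (goblet-like) to 62% (deep crypt secretory-like) of genes. Changes of that size can therefore be missed at these depths.

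The count of 0 genes stood under each setting run in epithelial and lymphoid cells, DESeq2 included (96 and 108 at an unadjusted p under 0.05 by edgeR with all mice and no added term). DESeq2 called 1 gene in stromal, 1 in myeloid and 2 in deep crypt secretory-like cells and put Spry2 in stromal cells at −0.024. With no expression filter 25 genes passed in myeloid, 13 in stem-like, 65 in cycling-like, 10 in colonocyte-like, 7 in goblet-like and 18 in deep crypt secretory-like cells, 14 in T and innate lymphoid cells, 28 in CD90-positive fibroblasts and 37 in macrophages. With 50 cells per mouse, which leaves out mouse 2, edgeR called 0 genes in cycling-like cells (559 at an unadjusted p under 0.05). With the mouse number term 2 genes passed in cycling-like cells, and with both terms 1 in stem-like cells and 10 in CD90-positive fibroblasts. Without the macrophages of 10 or more Jchain UMIs edgeR called 0 genes in macrophages (117 at an unadjusted p under 0.05). With an estimated correlation 0 lists passed in epithelial, stromal, lymphoid, cycling-like, colonocyte-like and goblet-like cells, and by fry likewise 0. In epithelial cells under 50% mitochondrial UMIs without clusters led by other lineages 3 lists passed. With the mouse number term 5 lists passed in lymphoid, 1 in stem-like and 0 in goblet-like cells, with both terms 6, 1 and 0, and with the sex term 0 in goblet-like cells. With equal cells per type, Axin2 was at 0.071, Cpe at 0.45, Pdia6 at 0.013 and the enteroendocrine median at 0.14. That sum held only 3 enteroendocrine-like cells per mouse. H2-DMa was at 0.0063 with the mouse number term and 0.0055 with both, and mt-Nd2 at −0.042 with the sex term. On the centred log ratio scale the differences were −0.0153 for B cells, −0.0130 for regulatory T cells, 0.0779 for goblet-like, 0.0825 for deep crypt secretory-like and 0.0432 for enteroendocrine-like cells. As shares of non-epithelial cells they were −4.29 percentage points for B cells, −0.0207 for macrophages and −0.129 for regulatory T cells, and in cells of 1000 or more UMIs −0.156 for cycling-like cells.

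Leaving out each mouse in turn gave these ranges. Epithelial log2 fold changes ran from −0.032 to 0.29 for Erbb3, −0.32 to 0.10 for Areg, −0.32 to 0.23 for Il17rb, −0.63 to 0.31 for H2-DMa, −1.01 to 1.36 for Nos2, −0.26 to 0.75 for mt-Nd6 and −0.26 to 0.71 for mt-Nd2. Spry2 ran from −0.61 (without mouse 7) to 0.068 (without mouse 8) in epithelial, −0.28 (7) to 0.23 (8) in stromal and −1.07 (1) to 0.64 (8) in lymphoid cells. List medians ran from −0.51 to 0.053 for proliferation and −0.071 to 0.39 for NF-kB targets in epithelial cells, −0.66 to 0.052 for ion transport in lymphoid cells and −0.00070 to 0.30 for mitochondrial genes in colonocyte-like cells. The lists that passed numbered 3 to 8 in epithelial, 1 to 9 in lymphoid, 0 to 1 in myeloid, 0 to 4 in stem-like, 2 to 4 in cycling-like, 0 to 4 in goblet-like and 0 to 3 in deep crypt secretory-like cells. Genes numbered 0 to 3 in myeloid, 0 to 1 in stem-like, 0 to 8 in cycling-like and 0 to 2 in deep crypt secretory-like cells, 0 to 1 in CD90-positive fibroblasts and 3 to 7 in macrophages. Differences in share, in percentage points, ran from −4.37 to 6.55 for B cells, −0.0863 to 0.910 for macrophages, −2.61 to 1.17 for goblet-like, −7.95 to 8.01 for colonocyte-like, −0.739 to 2.77 for cycling-like, −2.69 to 0.509 for deep crypt secretory-like and −0.232 to 0.0170 for enteroendocrine-like cells.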

Other observations

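Tests of genes in the authors' subtypes and the counts over other splits of the mice were chosen after the result was seen. In macrophages of 7 mice, genes of plasma cells and B cells were lower in KO-labelled mice: Jchain, the joining chain of secreted antibodies, had a log2 fold change of −6.94 (edgeR adjusted p = 2.81e-07). The antibody heavy chain gene Igha was at −6.88, Mzb1 at −4.81, Ly6d at −3.38, and the light chain genes Iglc1 and Iglv1 at −10.11 and −8.75, all past the threshold. DESeq2 called 7 genes. The count was 3 without mouse 2. In WT-labelled mice 1, 4 and 5, 1, 1 and 9 macrophages with 10 or more Jchain UMIs held 813 of 816, 1740 of 1762 and 8045 of 8150 Jchain UMIs, and KO-labelled mice had no such cell. Without these 11 cells edgeR called 0 genes, with 117 at an unadjusted p under 0.05.

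In the other 6 subtypes tested edgeR and DESeq2 called 0 genes, with unadjusted counts by edgeR of 140 in mature B cells, 193 in plasma cells, 157 in T and innate lymphoid cells, 209 in CD90-positive fibroblasts, 230 in CD90-positive Igfbp3 fibroblasts (7 mice) and 94 in ILC2. In CD90-positive fibroblasts Iglc1 passed without mouse 5 (−1.84, edgeR adjusted p = 0.0224). With sex and mouse number as terms 10 genes passed there by edgeR: Ptgs2 (0.95), which makes prostaglandins, Nr4a2 (0.94) and Gprc5a (0.96) were higher, and Fhl2 (−1.09) and the epithelial genes Fcgbp (−1.61), Lypd8 (−0.81), Cldn7 (−1.32), Tff3 (−1.02), Spink1 (−1.34) and Cyp2c55 (−1.17) were lower. Goblet genes had lower values in these fibroblasts (median −1.04, adjusted p = 4.04e-08; adjusted p = 0.182 with an estimated correlation) and in T and innate lymphoid cells (−1.06, adjusted p = 7.42e-06; adjusted p = 0.856 with an estimated correlation).

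Mid1, an X-linked gene that reaches into the mouse pseudoautosomal region, had log2 fold changes of −0.90 in epithelial, −1.57 in lymphoid, −1.31 in cycling-like, −0.41 in colonocyte-like and −0.18 in stromal cells. Of the feedback inhibitors of the pathway that Spry2 acts on, Spry1 stood at 0.51, Spry4 at −0.02 and Dusp6 at 0.44 in epithelial cells. None of these values passed in edgeR.

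The 8 mice can be split into groups of 4 in 35 ways, and the 7 mice of the macrophages in as many. As many genes as the real split were called by 35 splits in epithelial (0 genes, highest other 2467), stromal (0, 1332), lymphoid (0, 2332), myeloid (0, 17), stem-like (0, 605), colonocyte-like (0, 7), goblet-like (0, 504) and deep crypt secretory-like cells (0, 5), T and innate lymphoid cells (0, 347) and CD90-positive fibroblasts (0, 77). For the 1 gene of cycling-like cells it was 7 splits (highest other 26), and for the 6 genes of macrophages 2 (highest other 6). As many lists passed in 23 splits in epithelial (6 lists, highest other 12), 3 in stromal (8, 8), 31 in lymphoid (3, 14), 35 in myeloid (0, 4), 35 in stem-like (0, 5), 6 in cycling-like (4, 6), 12 in colonocyte-like (4, 6), 30 in goblet-like (1, 6) and 35 in deep crypt secretory-like cells (0, 5). Where the real count is 0 every split gives as many whatever the data hold, so those comparisons decide nothing. Chance cannot be excluded for the others, which are the genes of cycling-like cells and macrophages and the lists of epithelial, stromal, lymphoid, cycling-like, colonocyte-like and goblet-like cells. The split of mice 1 to 4 from mice 5 to 8 gave the highest count of genes in epithelial, stromal, lymphoid, stem-like, T and innate lymphoid cells and CD90-positive fibroblasts, which points to a structure of the samples. Splits unbalanced over these sides carry that structure, so counts over all splits can overstate how often chance gives as many. Splits balanced as the labels are were not counted apart. The mean mitochondrial share was 34.8 ± 7.47% in mice 1 to 4 and 14.9 ± 6.17% in mice 5 to 8, and the median UMIs per cell 1690.25 ± 142.5 and 2909.5 ± 553 (SD, n = 4 each, exact permutation p = 0.0286 for both). This division was chosen after seeing the data, so these p-values do not test it. Each label has 2 mice on either side, and with mouse number as a term edgeR called 0 genes in epithelial, stromal and lymphoid cells (203, 514 and 284 at an unadjusted p under 0.05). In KO-labelled mice the 2 sides also differ in sex, so sex and mouse number cannot be separated there.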
